A study of Antheraea pernyi with 6 samples.

How the data were processed

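Messenger RNA was profiled by deep sequencing in 6 cuticle samples of the Chinese oak silkmoth, Antheraea pernyi. The samples fell into 2 groups of 3, ApNPV-infected and Control. ApNPV is the nucleopolyhedrovirus of this moth, a baculovirus that packs its particles into protein crystals made of polyhedrin. Per the labels, cuticles were dissected, frozen on dry ice and extracted with Trizol, and the libraries were run on an Illumina HiSeq instrument. The labels give no larval stage, time after infection, dose or batch, and they do not say whether the 3 replicates of a group were separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

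The deposited table holds TPM, in which the transcripts of a library are scaled to a fixed total, for 39874 assembled transcript clusters in the 6 libraries, with the length of each cluster and its annotation. The cluster names are those of a Trinity assembly, and no genome build was involved. The submitters' processing notes name cutadapt, FastQC, Salmon and edgeR, without versions, order or roles. Each deposited TPM column sums to 1000000, to within rounding, so a value is a share of its library and the sequencing depth is unknown. No counting interval or detection floor can be given. A value of 0 is described as listed at 0, and no fold is given against it. The clusters are called transcripts here and are named by the protein descriptions in the table, which were present for 14029 of them (8442 had a Swiss-Prot description).

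Because the file holds TPM and no counts, each transcript was tested with limma 3.58.1 in R 4.3.3, with the mean-variance trend, on log2(TPM + 1). This was the contingency set for a table without counts, and no count-based test was run. A transcript was tested when it had at least 1 TPM in at least 3 of the 6 libraries. The model held the group only, tests were two-sided, and a Benjamini-Hochberg adjusted p of 0.05 was the threshold for calling a transcript higher or lower. Fold changes on the log2(TPM + 1) scale are smaller than the ratio of mean TPM for transcripts near or below 1 TPM. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.

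The share of baculovirus transcripts in each library was compared with a two-sided exact permutation test of the group means, for which 0.1 is the smallest p that 3 libraries against 3 can give. Libraries were compared by principal components and by correlation across transcripts, which are not independent replicates.

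30 gene lists were fixed as text patterns matched to the annotation. They cover chitin degradation, chitin synthesis, cuticle structural proteins, other chitin-binding proteins, cathepsins and lysosomal hydrolases, matrix metalloproteases with ADAMs and astacins, serine proteases, protease inhibitors, tanning and melanization, antimicrobial peptides, immune recognition and signalling, RNA interference, heat shock proteins, apoptosis, baculovirus, ribosomal proteins, translation factors, oxidative phosphorylation, glycolysis, proteasome and ubiquitin, autophagy, hormone response, basement membrane and adhesion, and detoxification and redox. The remaining lists are markers of muscle, fat body, hemocytes, silk gland, midgut, and trachea and nerve. Members passing the threshold were counted over all transcripts tested and adjusted over the list alone. Each list was also set against the other annotated transcripts with camera from limma, with a preset correlation of 0.01 between members and again with an estimated correlation, adjusted over the lists. With an estimated correlation, camera also takes the residual degrees of freedom of the model, which are far fewer. That alone can raise its p-values.

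Named transcripts follow a rule with 3 parts. The first takes the 10 largest rises and the 10 largest falls among annotated transcripts that passed the threshold, had the 3 libraries of one group all above those of the other, and lay in the upper part of the tested transcripts by mean abundance, split at their median. The second takes up to 4 members with the smallest p in each list. The third takes the most abundant member of the lists for chitin degradation, chitin synthesis, cuticle proteins, matrix metalloproteases, baculovirus and antimicrobial peptides. Abundance here is the mean over all 6 libraries. Transcripts outside the rule are said to be so where they appear.

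The test, the threshold, the lists, the rule and these alternatives were chosen before the data were examined: the replicate number as a block, leaving out each library, median-of-ratios scaling of the TPM, no filter, a mean of at least 5 TPM, a pseudocount of 0.1, limma without trend, at least a 2-fold change, removal of baculovirus transcripts, an estimated correlation, and baculovirus transcripts named for an Antheraea virus only. Alternatives for count data could not be run. Further alternatives were chosen after seeing the data: a wider baculovirus pattern, since the fixed one missed multicapsid viruses, removal of all polyhedrosis virus transcripts, removal of cuticle and muscle transcripts as well, removal of transcripts with a fly, microsporidian or mouse match, lists cleared of chance text matches, and scaling combined with the block or with the 2-fold minimum. GO terms of 10 to 300 transcripts were tested with camera in the same way, also after the data were seen.

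The test was checked on data simulated from the control means and residual spread of 36709 transcripts. At a simulated log2 change of 0.5, 1 and 2, only 154, 148 and 157 changed transcripts passed the filter, of 27501 to 27519 tested. The test recovered 5.19%, 28.4% and 64.3% of them. In the more abundant part of the transcripts the shares were 8%, 40.2% and 73.5%. False calls made up 0, 12.5 and 6.48% of all calls in these runs, from 0, 6 and 7 false calls. In the real comparison 25567 transcripts were called. An adjusted p under 0.05 is easier to reach when many transcripts change, so these shares do not give the recovery in the real comparison.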

Results

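The series title names the liquefaction of the cuticle of Antheraea pernyi after challenge with its nucleopolyhedrovirus, ApNPV. The 3 ApNPV-infected and 3 Control libraries were compared to ask which cuticle transcripts differed with infection. Values are given as mean TPM ± SD over the 3 libraries of a group, with adjusted p from limma. Replicates were close: among transcripts of at least 100 TPM the median coefficient of variation was 1.93% over 642 transcripts in the controls and 2.02% over 885 in the infected group. Across 36709 tested transcripts the mean Pearson correlation of log2 values was 0.931 within a group and 0.612 between groups, and the first principal component held 82.2% of the variance and parted the groups.

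Infected cuticle carried abundant viral transcripts and only a small remainder of the cuticle protein transcripts of the controls. Polyhedrin (TRINITY_DN8292_c1_g1), the protein of the viral occlusion bodies, stood at 51677 ± 715 TPM in the infected group against 1.96 ± 0.551 in the controls (adjusted p = 6.5e-09). The viral cathepsin (TRINITY_DN12502_c1_g1) reached 6051 ± 24.1 TPM against 0.177 ± 0.00577, and the viral chitinase A (TRINITY_DN7616_c0_g1) reached 3999 ± 11.3 against 0.113 ± 0.0115 (adjusted p = 5.1e-11 for both). These enzymes are known from other baculoviruses to help break down the host's body at the end of infection. The polyhedrin, cathepsin and chitinase clusters were 5292, 6992 and 3245 bases long. The TPM of each was not shown to be that of the gene that names it alone. In the opposite direction, 113 of the 122 tested cuticle structural proteins fell, and their summed abundance went from 256900 ± 1946 TPM in the controls to 12110 ± 134 TPM. The most abundant of them, larval cuticle protein LCP-17 (TRINITY_DN11978_c1_g1), fell from 39340 ± 498 to 1012 ± 20.1 TPM, a 38.9-fold difference (adjusted p = 1.5e-10).

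Transcripts annotated as baculovirus made up 7.38 ± 0.0858% of each infected library and 0.015 ± 0.00012% of each control library (two-sided exact permutation p = 0.1, the smallest possible with 3 against 3). A wider pattern chosen after seeing the data, which takes in multicapsid viruses, raised the infected share to 13.8 ± 0.107% against 0.0202% in the controls; without proteins that have insect relatives the share was 13.8 ± 0.108% against 0.000458 ± 0.0000962%. Of the 32 tested members of the fixed baculovirus list, 23 rose and 6 fell, and 21 rose and 6 fell after scaling. The camera call of this list (adjusted p = 0.0278, higher) was lost without a filter (adjusted p = 0.0567), with a pseudocount of 0.1 (0.0585) and with an estimated correlation (0.0869), while the 82 tested transcripts of the wider pattern gave an adjusted p of 2.2e-13, and an adjusted p of 0.0134 with an estimated correlation. With infected replicate 1, 2 or 3 left out, 16, 17 and 17 members of the fixed list were left to test, since the filter of 3 libraries then bars transcripts seen only in the infected group, and the adjusted p of 0.552, 0.461 and 0.557 carries no weight. The 6 that fell were UDP-glycosyltransferases with moth best matches, which the pattern took in by their resemblance to a viral enzyme. All of the 10 largest rises under the naming rule had a polyhedrosis virus as Swiss-Prot match. Besides polyhedrin, cathepsin and chitinase they were protein p26 (TRINITY_DN12352_c1_g6) at 8121 TPM, late expression factor 2 (TRINITY_DN8292_c1_g3) at 6519 TPM, a spheroidin-like protein (TRINITY_DN603_c0_g1) at 5261 TPM, protein Early 65 kDa (TRINITY_DN13652_c1_g4) at 4180 TPM, occlusion-derived virus envelope protein E25 (TRINITY_DN13128_c0_g4) at 3666 TPM, a polynucleotide kinase/RNA ligase (TRINITY_DN13652_c1_g3) at 3155 TPM and a superoxide dismutase (TRINITY_DN10759_c2_g2) at 2872 TPM. Of these 7, protein p26 had the highest control mean, at 0.353 TPM.

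In all, 20775 transcripts were higher and 4792 lower in the infected group, and 15104 and 3484 of them changed at least 2-fold. The balance of these counts depended on the scale. The median log2 change of all tested transcripts was 0.86 in the deposited TPM and 0.037 after median-of-ratios scaling, and the share of calls that were higher went from 81.3% to 47.2%. After scaling, 8496 transcripts were higher and 9522 lower. At a 2-fold minimum the scaled counts were 4243 higher and 6750 lower, with 38.6% of calls higher. Scaling lowers the infected values relative to the controls as a whole, and 1171 that were first called higher were called lower after it. The libraries also differed in how abundance was spread: the 100 most abundant transcripts held 42.7 to 43% of an infected library and 61.4 to 62.1% of a control library. Group counts below are therefore given under the deposited TPM and again after scaling.

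**Figure D1:**
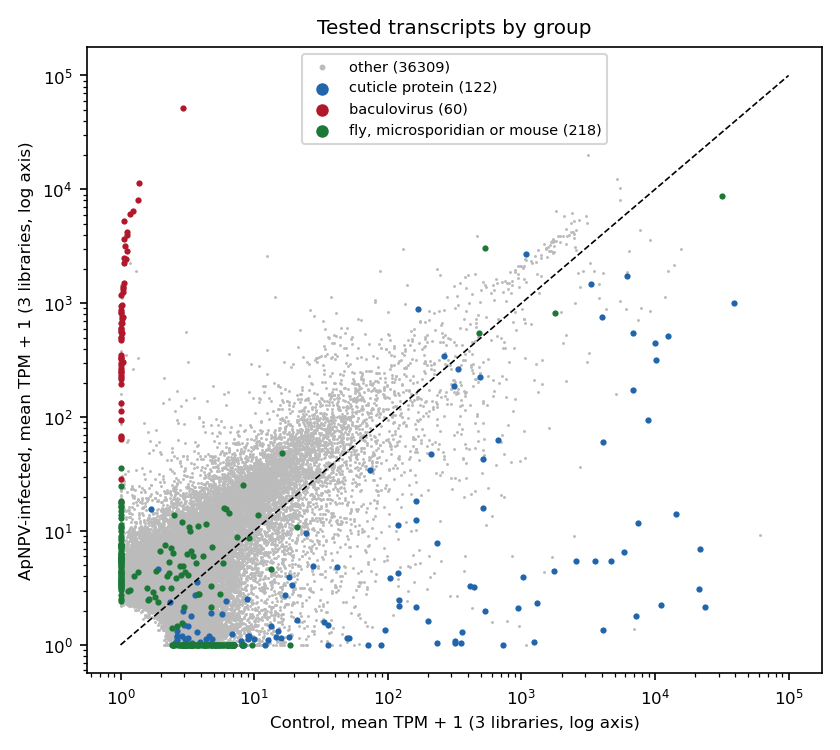
Mean TPM + 1 of each tested transcript in the 3 Control libraries (x, log axis) and the 3 ApNPV-infected libraries (y, log axis), with the line of equality dashed and points coloured by annotation. Baculovirus transcripts stand along the left edge, up to polyhedrin at 51677 TPM, and 113 of 122 cuticle proteins lie low on the right; the class of fly, microsporidian or mouse matches holds points at 0 in one group as well as some, such as an actin, that were abundant in both.

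Among the cuticle structural proteins, 5 rose and 113 fell, with a median log2 change of -3.32; after scaling 4 rose and 116 fell, with a median of -4.09. Muscle markers fell alongside, from 98770 to 21460 TPM in sum. Against other annotated transcripts the cuticle list lay lower (camera adjusted p = 6.1e-58, and adjusted p = 0.000693 with an estimated correlation). Cuticular protein 11 (TRINITY_DN11219_c0_g4) fell from 23712 ± 235 to 1.14 ± 0.69 TPM, and cuticle protein 66 (TRINITY_DN10619_c3_g1) from 21212 ± 366 to 2.1 ± 1.41 TPM. Cuticle protein 1 (TRINITY_DN9250_c0_g2) fell from 21603 ± 219 to 5.92 ± 0.251 TPM. Of the 10 largest falls, 9 were cuticle proteins; the rest of them were an RR-2 motif 59-like protein (TRINITY_DN13962_c1_g2) at 11121 TPM in controls and 1.25 in the infected group, pupal cuticle protein PCP52 (TRINITY_DN12063_c0_g1) at 7261 and 0.783, a cuticle protein 1-like transcript (TRINITY_DN9789_c1_g1) at 4109 and 0.363, a cuticle protein 3-like transcript (TRINITY_DN11031_c1_g4) at 5844 and 5.51, and an RR-2 motif 63 protein (TRINITY_DN13581_c2_g4) at 3576 and 4.49. A putative cuticle protein (TRINITY_DN4017_c0_g1) had 722 ± 16.9 TPM in the controls and was listed at 0 in all 3 infected libraries. The tenth was an odorant binding protein (TRINITY_DN14602_c0_g1), at 953 ± 18.7 TPM in controls and 0.457 ± 0.15 in the infected group. Falls were also seen for flexible cuticle protein 12 (TRINITY_DN13701_c0_g1), from 8883 to 92.5 TPM, for larval cuticle protein 16/17 (TRINITY_DN4339_c0_g1), from 6847 to 171 TPM, and for an unlabelled cuticle list member (TRINITY_DN8788_c3_g1), from 4691 to 4.49 TPM.

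**Figure D2:**
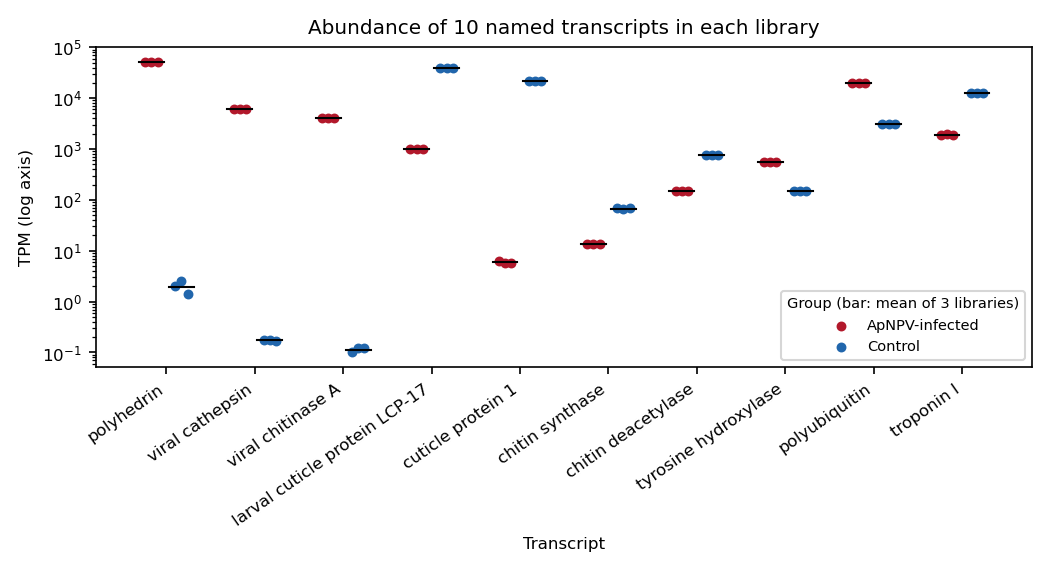
TPM (log axis) of 10 named transcripts in each library, with 3 points per group and a bar at the mean of the group. Viral polyhedrin, cathepsin and chitinase A lie between 3986 and 52485 TPM in infected libraries and below 3 TPM in controls, cuticle protein 1 falls from 21603 to 5.92 TPM, chitin synthase from 67.6 to 13.6 TPM, and tyrosine hydroxylase and polyubiquitin are higher in the infected group.

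While the viral chitinase rose, the host enzymes of chitin turnover with the smallest p fell. Chitin deacetylase (TRINITY_DN12749_c4_g4), which removes acetyl groups from chitin, fell from 772 ± 2.67 to 150 ± 1.4 TPM (adjusted p = 1.8e-09). Chitinase 3 (TRINITY_DN9673_c0_g3) fell from 523 ± 11.7 to 45.2 ± 3.03 TPM and chitinase 7 (TRINITY_DN13189_c0_g5) from 37 ± 0.247 to 2.73 ± 0.104 TPM. Without the viral enzyme, the 19 other members of the chitin degradation list summed to 1885 ± 6.99 TPM in controls and 624.5 ± 2.69 TPM in the infected group. By number the list of 20 split evenly, with 10 higher and 8 lower, and 4 higher and 9 lower after scaling. Its median log2 change was 0.54, yet its mean lay below that of other transcripts by 0.04 and camera placed it lower (adjusted p = 0.043, and adjusted p = 0.117 with an estimated correlation); after scaling the median was -0.11. That call was also lost after scaling (adjusted p = 0.253), without a filter (adjusted p = 0.0552) and without the trend (adjusted p = 0.0552), and the difference in means ranged from -0.71 to -0.21 with each of the 6 libraries left out in turn; without an infected library the viral chitinase no longer passed the filter. Chitin synthase (TRINITY_DN13720_c1_g1), the enzyme that makes the polymer, fell from 67.6 ± 1.29 to 13.6 ± 0.113 TPM (adjusted p = 7.6e-08). The other members of the synthesis list with the smallest p are enzymes of its supply and fell. Glutamine-fructose-6-phosphate aminotransferase (TRINITY_DN10540_c0_g1) fell from 31.8 to 11.1 TPM and glucosamine-6-phosphate N-acetyltransferase (TRINITY_DN11907_c1_g1) from 23 to 10.8 TPM. Hexokinase (TRINITY_DN13015_c2_g1), the list's most abundant member by the mean over all 6 libraries, fell from 59.8 to 24.8 TPM. The chitin synthesis list of 16 had 8 higher and 7 lower, but 0 higher and 9 lower after scaling (camera adjusted p = 0.00716, lower; adjusted p = 0.0648 with an estimated correlation). Of 28 other chitin-binding proteins 7 rose and 12 fell, and 1 rose and 16 fell after scaling (adjusted p = 3.5e-05, lower; adjusted p = 0.128 with an estimated correlation). They included a peritrophin-like cuticular protein, 3-D1 (TRINITY_DN9266_c0_g1), which fell from 102 to 2.87 TPM, a mucin-5AC-like transcript with a cuticle protein match (TRINITY_DN9982_c0_g1), which fell from 357 to 0.303 TPM, an integumentary mucin (TRINITY_DN9881_c2_g1), which fell from 9.65 to 0.1 TPM, and mucin-17 (TRINITY_DN8801_c0_g1), which rose from 35.3 to 127 TPM.

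Proteases went both ways. Of 21 cathepsins and lysosomal hydrolases 11 rose and 6 fell, and 6 rose and 6 fell after scaling (camera adjusted p = 0.63). Without viral members and chance text matches 8 of 17 rose and 6 fell, and 4 rose and 6 fell after scaling. The host members with the smallest p rose: cathepsin L (TRINITY_DN11985_c0_g1), from 61.6 ± 2.17 to 333 ± 5.12 TPM, a prosaposin (TRINITY_DN11054_c1_g3), from 52.7 to 249.6 TPM, and lysosomal aspartic protease (TRINITY_DN15047_c0_g4), from 27 to 160.5 TPM. In the list of matrix metalloproteases, ADAMs and astacins, 6 of 15 rose and 3 fell, and 2 rose and 6 fell after scaling (adjusted p = 0.33). Its most abundant member by the mean over all 6 libraries was MMP variant 1 (TRINITY_DN14393_c0_g1), of an enzyme class that cuts extracellular matrix. It fell from 42.4 ± 1.27 to 18.6 ± 0.951 TPM. Both named ADAMTS proteases rose, from 4.48 to 25.7 TPM for TRINITY_DN11505_c0_g1 and from 1.93 to 7.81 TPM for TRINITY_DN14158_c4_g1. An ADAM 17-like protease (TRINITY_DN10721_c0_g6) rose from 2.04 to 6.03 TPM but not after scaling (adjusted p = 0.0848). Of 112 members of the serine protease list 45 rose and 50 fell, and 24 rose and 70 fell after scaling (adjusted p = 1.3e-05, lower; 0.0133 as adjusted p with an estimated correlation). Its 4 members with the smallest p were inhibitors, which the pattern took in; without inhibitors, 22 of 67 rose and 32 fell, and 7 rose and 47 fell after scaling. Of 65 protease inhibitors 24 rose and 33 fell, and 13 rose and 43 fell after scaling (adjusted p = 2.5e-06, lower). Serpin 2 (TRINITY_DN9432_c4_g1) rose from 86.8 ± 1.29 to 1904 ± 28.8 TPM, an antichymotrypsin-2-like transcript (TRINITY_DN13992_c1_g2) from 36.4 to 1127 TPM, a serpin-like transcript (TRINITY_DN14360_c0_g1) from 448 to 1793 TPM, and serine protease inhibitor 4 (TRINITY_DN12509_c0_g1) from 385.8 to 1349 TPM.

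In tanning and melanization, which harden and darken cuticle, 11 of 28 transcripts rose and 10 fell, and 5 rose and 23 fell after scaling (camera adjusted p = 0.00258, lower; 0.045 as adjusted p with an estimated correlation). Tyrosine hydroxylase (TRINITY_DN11192_c0_g1), which makes DOPA, rose from 149 ± 2.63 to 564 ± 1.18 TPM (adjusted p = 1.0e-08), also after scaling. A prophenoloxidase-activating proteinase (TRINITY_DN14018_c1_g2) rose from 136 to 270.5 TPM in the deposited values and fell by 0.14 on the log2 scale after scaling. Prophenoloxidase activating factor 1 (TRINITY_DN11607_c1_g1) fell from 108 to 63.5 TPM and activating proteinase 3 (TRINITY_DN10655_c1_g1) from 60.5 to 35.1 TPM. Of 77 transcripts of the hormone response list 24 rose and 37 fell, and 9 rose and 47 fell after scaling (adjusted p = 3.4e-08, lower; 0.0147 as adjusted p with an estimated correlation). A juvenile hormone esterase-related transcript (TRINITY_DN15083_c3_g1) rose from 138 ± 7.05 to 1453 ± 53.6 TPM, and the ecdysone-inducible receptor E75 (TRINITY_DN10037_c0_g2) rose from 13.6 to 47.9 TPM. A juvenile hormone binding protein (TRINITY_DN9803_c2_g1) fell from 513 to 132 TPM and an ecdysteroid-regulated 16 kDa protein (TRINITY_DN7217_c0_g1) from 64.1 to 16.4 TPM.

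Immune transcripts moved both ways. Of 25 antimicrobial peptide transcripts 9 rose and 15 fell, and 6 rose and 17 fell after scaling (camera adjusted p = 2.3e-05, lower; 0.0165 as adjusted p with an estimated correlation). Markers of fat body and hemocytes, tissues that make such peptides, lay lower as well, with 21 and 19 of 34 lower and 29 of each lower after scaling. A cecropin-like peptide (TRINITY_DN14249_c2_g3) fell from 279 ± 7.19 to 38.2 ± 0.599 TPM and cecropin-A (TRINITY_DN8578_c2_g4) from 239 to 56.7 TPM. The most abundant member, a lysozyme-like transcript with a fly as best match (TRINITY_DN9660_c0_g2), fell from 1798 to 821.7 TPM, while moricin-like peptide C4 (TRINITY_DN12689_c4_g1) rose from 40.2 ± 5.75 to 812 ± 63 TPM. Of 76 members of the immune recognition and signalling list 29 rose and 28 fell, and 12 rose and 45 fell after scaling (adjusted p = 0.000148, lower; 0.0157 as adjusted p with an estimated correlation). Cleared of chance text matches, its 44 tested members gave an adjusted p of 0.00225, and an adjusted p of 0.0627 with an estimated correlation, and at a mean of at least 5 TPM the list call was lost (adjusted p = 0.125). The Toll receptor TRINITY_DN13130_c0_g5 rose from 33.3 to 178 TPM and TRINITY_DN13130_c0_g2 from 10.2 to 72.2 TPM. Cactus (TRINITY_DN15043_c0_g3), an inhibitor in the Toll pathway, rose from 43.2 ± 2.92 to 505 ± 17.9 TPM, and a beta-1,3-glucan recognition protein (TRINITY_DN9110_c1_g1) rose from 40.5 to 146 TPM. In RNA interference, an antiviral system of insects, 10 of 11 transcripts rose and 0 fell, but 3 rose and 0 fell after scaling (adjusted p = 0.106; 0.0439 after scaling with the replicate block and 0.0494 without baculovirus, cuticle and muscle transcripts). Argonaute 2 (TRINITY_DN13845_c0_g1) went from 6.64 to 16.4 TPM, with a scaled adjusted p of 0.14, and R2D2 (TRINITY_DN14890_c1_g1) from 9.25 to 19.9 TPM, with a scaled log2 change of -0.022. A partial argonaute-2-like transcript (TRINITY_DN5625_c0_g3) had 2.39 TPM in the infected group and was listed at 0 in controls. A BRISC complex member (TRINITY_DN10250_c0_g3), a deubiquitinase subunit taken in by the pattern, rose from 3.34 to 14.8 TPM.

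Of 256 proteasome and ubiquitin transcripts 224 rose and 4 fell, and 152 rose and 20 fell after scaling (camera adjusted p = 1.1e-07, higher; 0.0133 as adjusted p with an estimated correlation). Polyubiquitin (TRINITY_DN11633_c0_g4) rose from 3154 ± 11.2 to 19906 ± 190 TPM (adjusted p = 4.4e-10). Members with viral matches also belong to the list: a viral ubiquitin-like protein (TRINITY_DN12145_c0_g10) at 1169 TPM against 0.0133 and the ligase IE2 (TRINITY_DN10437_c0_g2) at 550.4 against 0.02. All 13 autophagy transcripts rose, and 7 rose and 0 fell after scaling (adjusted p = 0.0484, higher; adjusted p = 0.128 with an estimated correlation). The list call was also lost without Control replicate 1, 2 or 3 (adjusted p = 0.0916, 0.0534 and 0.0847), without a filter (0.0576), at a mean of at least 5 TPM (0.244), with a pseudocount of 0.1 (0.0613), without baculovirus transcripts (0.0531) and without all polyhedrosis virus transcripts (0.0564). Sequestosome-1 (TRINITY_DN12722_c0_g1), the receptor for ubiquitin-tagged cargo, rose from 48.1 ± 2.3 to 297 ± 5.93 TPM, ATG101 (TRINITY_DN7440_c0_g1) from 1.53 to 13 TPM, ATG12 (TRINITY_DN11115_c1_g2) from 7.34 to 20.3 TPM and ATG2 (TRINITY_DN14817_c0_g1) from 1.38 to 8.01 TPM. Of 74 heat shock proteins 57 rose and 13 fell, and 30 rose and 23 fell after scaling (adjusted p = 0.223). HSP90 (TRINITY_DN8492_c0_g1) rose from 263 to 879 TPM and the 70 kDa cognate (TRINITY_DN12703_c0_g1) from 1806 to 6402 TPM. 2 small heat shock proteins fell, from 6414 to 2860 TPM for TRINITY_DN14603_c3_g1 and from 101 to 13.1 TPM for G7 (TRINITY_DN7422_c0_g1). Of 47 transcripts in the apoptosis list 29 rose and 16 fell, and 10 rose and 21 fell after scaling (adjusted p = 0.139, and 0.0362 at a mean of at least 5 TPM). Cleared of viral members and chance text matches, the list kept 19 members, of which 18 rose and 1 fell, and 5 rose and 2 fell after scaling (adjusted p = 0.0822, with the direction turned from lower to higher). The largest changes of the full list were viral transcripts with an apoptosis inhibitor as Swiss-Prot match. TRINITY_DN10805_c2_g4, which the other annotation labels cap specific mRNA, stood at 823 against 0.0167 TPM. TRINITY_DN10759_c1_g2, a cluster of 3779 bases, stood at 670.1 against 0.0133 TPM. The TPM of each was not shown to be that of an apoptosis inhibitor gene alone. Cytochrome c (TRINITY_DN11288_c2_g1) fell from 297 to 128 TPM and COX16 (TRINITY_DN11986_c1_g1), an oxidase assembly factor taken in by the pattern, rose from 37.5 to 245 TPM.

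Translation factors rose in 74 of 84 transcripts and fell in 3, and rose in 42 and fell in 19 after scaling (camera adjusted p = 1.4e-05, higher; 0.0133 as adjusted p with an estimated correlation). Elongation factor 2 (TRINITY_DN14515_c1_g1) rose from 316 ± 2.45 to 916 ± 7.99 TPM, elongation factor 1 alpha (TRINITY_DN8058_c0_g1) from 2378 to 6164 TPM and 1 beta' (TRINITY_DN7430_c0_g1) from 424 to 1201 TPM. Factor 1 gamma (TRINITY_DN10495_c0_g4) rose from 485 to 1015 TPM, with a scaled log2 change of -0.064. Of 311 ribosomal proteins 228 rose and 74 fell, and 77 rose and 177 fell after scaling. Camera did not call the list in the deposited TPM (adjusted p = 0.363) but placed it lower than other annotated transcripts after scaling (adjusted p = 0.00232). Of the 74 that fell, 73 had a fly as best match and all 73 were listed at 0 in the infected libraries, and 31 that rose had a microsporidian match. Without transcripts of fly, microsporidian or mouse match, chosen after seeing the data, 197 of 207 ribosomal proteins rose and 1 fell (adjusted p = 3.1e-09, higher; 0.0145 as adjusted p with an estimated correlation), but 47 rose and 100 fell after scaling (adjusted p = 0.042, lower). Among the named members, 40S S27 (TRINITY_DN10952_c1_g2) went from 2346 to 5084 TPM, 60S L6 (TRINITY_DN8241_c2_g1) from 749.9 to 1572 TPM and 60S L10a (TRINITY_DN11721_c3_g1) from 1184 to 2366 TPM, all with the sign reversed after scaling. 60S L4 (TRINITY_DN9175_c2_g4) rose from 494 to 1311 TPM under both.

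Of 102 oxidative phosphorylation transcripts 21 rose and 70 fell, and 6 rose and 89 fell after scaling (camera adjusted p = 8.0e-21, lower; 0.0133 as adjusted p with an estimated correlation). ATP synthase subunit a (TRINITY_DN1077_c0_g1), encoded by the mitochondrion, fell from 1063 ± 34.1 to 329 ± 7.41 TPM. Subunit c (TRINITY_DN7247_c0_g1) fell from 1182 to 650.4 TPM, subunit d (TRINITY_DN8136_c0_g1) from 460 to 216 TPM and the succinate dehydrogenase flavoprotein (TRINITY_DN13449_c0_g1) from 47.6 to 11.9 TPM. The muscle markers, from a tissue rich in these enzymes and those of glycolysis, fell alongside from 98770 to 21460 TPM in sum. In glycolysis 4 of 18 rose and 12 fell, and 3 rose and 13 fell after scaling (adjusted p = 5.8e-07, lower; 0.0165 as adjusted p with an estimated correlation). Aldolase (TRINITY_DN12916_c0_g1) fell from 331 to 72.8 TPM and enolase (TRINITY_DN11092_c1_g2) from 247 to 74.7 TPM, while lactate dehydrogenase (TRINITY_DN8491_c2_g4), which turns pyruvate to lactate, rose from 38.5 ± 0.394 to 443 ± 4.69 TPM. Enolase-phosphatase E1 (TRINITY_DN8031_c0_g1), a methionine salvage enzyme taken in by the pattern, fell from 518 to 136 TPM. Of 163 detoxification and redox transcripts 67 rose and 61 fell, and 27 rose and 99 fell after scaling (adjusted p = 1.1e-05, lower, and 0.06 at a mean of at least 5 TPM). Cytochrome P450 4G49 (TRINITY_DN11971_c0_g1), of a family that makes cuticular hydrocarbons, rose from 2.2 ± 0.29 to 305 ± 4.79 TPM, and an integumental esterase (TRINITY_DN15178_c1_g4) rose from 103.5 to 477 TPM. Of 95 basement membrane and adhesion transcripts 32 rose and 24 fell, and 10 rose and 48 fell after scaling (adjusted p = 8.6e-05, lower; 0.0149 as adjusted p with an estimated correlation; 0.06 at a mean of at least 5 TPM). A collagen (TRINITY_DN9144_c0_g5) fell from 403 to 52 TPM and a collagen and EGF domain protein (TRINITY_DN7500_c0_g1) from 87.4 to 8.79 TPM. An integrin beta (TRINITY_DN11956_c1_g7) rose from 9.33 to 37.6 TPM. A transcript labelled low density lipoprotein receptor (TRINITY_DN11620_c0_g1), with nidogen-1 as its Swiss-Prot match, rose from 1.56 to 113 TPM.

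Markers of other tissues moved with the groups as well. Muscle markers summed to 98770 ± 1137 TPM in controls and 21460 ± 257 TPM in the infected group. Of 87 muscle markers 33 rose and 44 fell, and 10 rose and 56 fell after scaling (camera adjusted p = 1.4e-10, lower; adjusted p = 0.0503 with an estimated correlation, and 0.0311 for the 71 members left once chance text matches were cleared). Troponin I (TRINITY_DN15007_c0_g3) fell from 12511 ± 153 to 1922 ± 10.7 TPM, both troponin T transcripts fell, from 9155 to 852 TPM for TRINITY_DN12611_c0_g1 and from 11983 to 1139 TPM for TRINITY_DN11745_c1_g2, and muscle myosin heavy chain (TRINITY_DN15082_c1_g1) fell from 6024 to 885 TPM. Of 34 fat body markers 4 rose and 21 fell, and 3 rose and 29 fell after scaling (adjusted p = 1.4e-10, lower; 0.0133 as adjusted p with an estimated correlation), with apolipophorin-III (TRINITY_DN11586_c5_g1) falling from 205 to 2.93 TPM, arylphorin (TRINITY_DN7790_c0_g1) falling from 39.7 to 1.91 TPM, microvitellogenin (TRINITY_DN9589_c1_g3) rising from 32.9 to 202 TPM and the lipophorin receptor (TRINITY_DN11145_c0_g1) rising from 13.3 to 70.8 TPM. Of 34 hemocyte markers 8 rose and 19 fell, and 1 rose and 29 fell after scaling (adjusted p = 1.2e-07, lower; 0.0147 as adjusted p with an estimated correlation). Hemolin (TRINITY_DN14274_c3_g4) went from 372 to 729.5 TPM, with a scaled log2 change of -0.16, a second hemolin transcript (TRINITY_DN14274_c3_g1) fell from 15.7 to 0.43 TPM, and hemocyte aggregation inhibitor (TRINITY_DN9415_c0_g2) fell from 309 to 209 TPM. Of 9 midgut markers 4 rose and 4 fell, and 1 rose and 8 fell after scaling (adjusted p = 0.139, and 0.0242, lower, after scaling). Aminopeptidase NPEPL1 (TRINITY_DN12939_c0_g1), a chance text match to the pattern for aminopeptidase N, rose from 7.47 to 74 TPM. Aminopeptidase N (TRINITY_DN11467_c1_g1) fell from 30.3 to 18.2 TPM, a peritrophic membrane protein (TRINITY_DN15570_c0_g1) from 2.01 to 0.07 TPM and an alkaline phosphatase (TRINITY_DN8467_c4_g2) from 1.62 to 0.09 TPM. Of 10 tracheal and neural markers 7 rose and 2 fell, and 1 rose and 4 fell after scaling (adjusted p = 0.955). Synaptobrevin (TRINITY_DN15142_c2_g6), with vesicle-associated membrane protein 7 as its Swiss-Prot match, rose from 2.02 to 11.2 TPM. Synaptotagmin-like 4 (TRINITY_DN13793_c0_g1) fell from 35.1 to 21.3 TPM. ELAV-like transcripts went from 12.7 to 27.9 TPM (TRINITY_DN6665_c0_g1, scaled adjusted p = 0.949) and from 9.33 to 17.5 TPM (TRINITY_DN5042_c0_g1, with a scaled log2 change of -0.20). The only silk gland marker, seroin2 (TRINITY_DN14040_c0_g1), fell from 2.81 to 0.48 TPM.

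**Figure D3:**
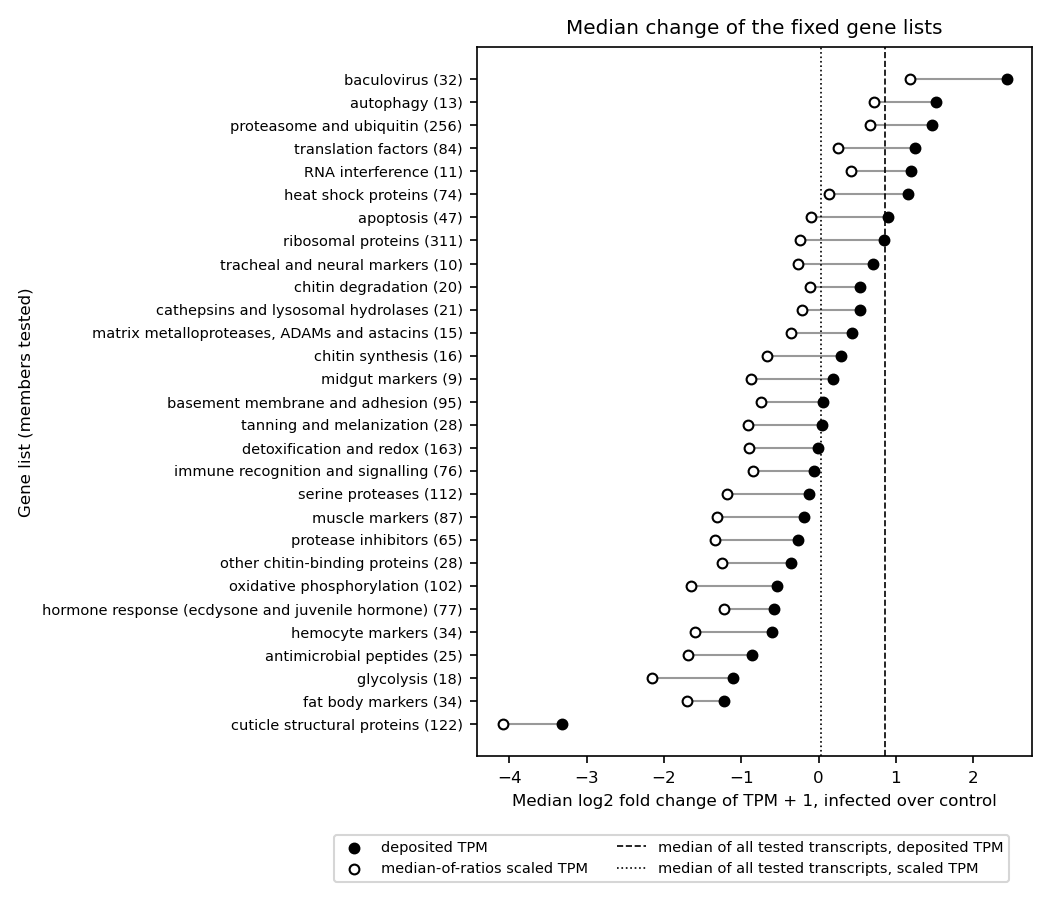
Median log2 fold change of TPM + 1, infected over control, for each gene list with at least 9 tested members, in deposited TPM (filled) and after median-of-ratios scaling (open), with the medians of all tested transcripts as vertical lines at 0.86 and 0.037. Cuticle structural proteins lie farthest down, at -3.32 and -4.09. Proteasome and ubiquitin, autophagy, baculovirus, translation factors, RNA interference and heat shock proteins lie above the line for all transcripts on both scales.

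Adjusted over the list alone, the counts equalled those over all transcripts tested for every list except the following. Higher calls became 58 for heat shock proteins, 229 for ribosomal proteins, 229 for proteasome and ubiquitin, 35 for muscle and 5 for fat body. Lower calls became 1 for matrix metalloproteases, ADAMs and astacins, 51 for serine proteases, 29 for immune recognition and signalling, 38 for hormone response, 23 for basement membrane and adhesion, 62 for detoxification and redox and 22 for fat body. Of the 29 lists that camera could test, 21 passed with the preset correlation and 15 with an estimated correlation. The 6 that passed only with the preset one were chitin degradation, chitin synthesis, other chitin-binding proteins, muscle, autophagy, and baculovirus. For chitin degradation (-0.026), chitin synthesis (-0.023), autophagy (-0.057) and baculovirus (-0.0055) the estimated correlation lay below the preset 0.01. Correlation between members thus does not account for the loss of those calls, which came with fewer degrees of freedom. For other chitin-binding proteins (0.143) and muscle (0.0739) the estimate lay above it. Protease inhibitors and detoxification and redox kept an adjusted p of 0.0133. Camera ranks a list by its moderated statistics, and for 4 lists that did not pass its direction differed from the sign of the mean difference: cathepsins and lysosomal hydrolases (0.13), apoptosis (0.20), ribosomal proteins (-0.19) and tracheal and neural markers (-0.10).

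The groups also differed in transcripts matched to other organisms, chosen after their values were seen. Of 160 transcripts with a fly or mosquito as best match in the annotation, a set that includes a few with viral Swiss-Prot matches, 89 were listed at 0 in all infected libraries and above 0 in all controls, where they summed to 319 ± 23.2 TPM. Of 66 with a microsporidian Swiss-Prot match, 65 were found only in the infected libraries, at 350 ± 15.7 TPM, and they included 5 spore wall proteins. Of 10 with a mouse match, 8 were found only in the infected libraries, at 101.5 ± 2.27 TPM, and they included milk proteins: 5 casein transcripts and whey acidic protein at 34.7 ± 3.03 TPM. Counts moved by over 1.5 times when single libraries were left out, where fewer transcripts passed the filter, which stayed at 3 libraries: without infected replicate 1, 2 or 3 the higher calls became 13672, 13703 and 13586, and without Control replicate 1, 2 or 3 the lower calls became 2329, 2406 and 2432.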

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

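The alternatives that remove cuticle and muscle, all polyhedrosis virus or fly, microsporidian and mouse transcripts, the cleared lists, the wider baculovirus patterns and the scaling combined with another change were chosen after the results were seen. The replicate number as a block gave 20225 higher and 4655 lower transcripts and 21 lists, but the numbers pair no libraries: deviations from the group mean correlated between -0.0089 and 0.00657 across same and different numbers alike. All 123 named transcripts kept their direction and call under the block, no filter, a pseudocount of 0.1 and no trend. Depth cannot be judged from TPM, and the RLE and DESeq2 alternatives need counts and were not run.

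Leaving out a library gave 13586 to 19529 higher and 2329 to 4436 lower calls. Fewer transcripts then pass the filter and each test has fewer libraries, and these were not told apart. Median-of-ratios scaling gave 8496 higher and 9522 lower, with the block 7371 and 8891, and 4243 higher and 6750 lower with a 2-fold minimum. A mean of 5 TPM gave 8464 and 1694, with fewer transcripts tested. The baculovirus share of the infected libraries was 0.605% for transcripts named for an Antheraea virus, of which there was only 1. It was 13.8% for the wider pattern and 13.8% (13.79) without proteins that have insect relatives. These shares differ by construction. The correlation between groups was 0.645 to 0.674 with a library left out, 0.625 without a filter, 0.517 at a mean of 5 TPM, 0.428 with pseudocount 0.1, 0.619 without baculovirus, cuticle and muscle and 0.625 without polyhedrosis virus. The cause was not tested for these last 6 values.

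List calls of chitin degradation, autophagy, baculovirus, immune recognition and signalling, basement membrane and adhesion, and detoxification and redox ended under at least 1 alternative besides the estimated correlation, with the baculovirus list keeping 16 to 17 of its 32 members past the filter when an infected library is left out, and ribosomal proteins, midgut, RNA interference and apoptosis gained a call under at least 1; the other causes were not tested. Mean log2 differences of lists from other transcripts changed sign as follows, and the cause was not tested except where stated. With a library left out in turn, the difference ranged from -0.32 to 0.36 for cathepsins and lysosomal hydrolases (negative without any infected replicate, where the viral cathepsin no longer passed the filter), from -0.011 to 0.18 for heat shock proteins (negative without Control replicate 2), from -0.049 to 0.16 for apoptosis (negative without any infected replicate, where 0 of its 2 viral members passed the filter), from -0.48 to 0.46 for ribosomal proteins (positive without any Control replicate, where 0 of 73 fly-matched members passed the filter) and from -0.29 to 0.092 for tracheal and neural markers (positive without any infected replicate). With pseudocount 0.1, chitin degradation became 0.042 and cathepsins -0.18. Cathepsins became -0.44 without baculovirus, -0.50 without baculovirus, cuticle and muscle, -0.42 without polyhedrosis virus and -0.59 in the cleared list, all of which drop the viral cathepsin. Heat shock proteins became -0.031 with scaling, with or without the block. At a mean of 5 TPM, heat shock proteins became -0.26, ribosomal proteins 0.14 and midgut markers 0.096. Apoptosis became -0.26 without baculovirus, cuticle and muscle and -0.12 without polyhedrosis virus. Ribosomal proteins became 0.43 without fly, microsporidian and mouse transcripts, which drops those listed at 0 in the infected group. With scaling, with or without the block, 8 named transcripts reversed, by the shift of all transcripts: TRINITY_DN14018_c1_g2 (-0.14), TRINITY_DN14890_c1_g1 (-0.022), TRINITY_DN10952_c1_g2 (-0.013), TRINITY_DN8241_c2_g1 (-0.061), TRINITY_DN11721_c3_g1 (-0.13), TRINITY_DN10495_c0_g4 (-0.064), TRINITY_DN14274_c3_g4 (-0.16) and TRINITY_DN5042_c0_g1 (-0.20).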

Other observations

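All tests in this part were chosen after the results they measure were seen, except the counts over other splits of the libraries. Of 1102 GO terms tested against 8780 annotated transcripts with camera, 67 lay higher and 119 lower at an adjusted p of 0.05 with the preset correlation. With an estimated correlation, and the fewer degrees of freedom that go with it, 0 lay higher and 0 lower. How much of this loss was owed to correlation between members was not tested. All 25 transcripts of the proteasome complex rose, under both scalings, with a median log2 change of 3.11 against 0.96 for the background (adjusted p = 6.1e-06; adjusted p = 0.166 with an estimated correlation). Of 137 transcripts of mRNA splicing via the spliceosome 130 rose and 1 fell, and 80 rose and 11 fell after scaling (adjusted p = 6.7e-06; adjusted p = 0.202 with an estimated correlation). Of 42 transcripts of DNA replication 41 rose, and 23 rose and 2 fell after scaling (adjusted p = 0.0217; adjusted p = 0.238 with an estimated correlation). Among terms that lay lower, juvenile hormone biosynthesis had 0 of 12 transcripts higher and 8 lower, and 11 lower after scaling (adjusted p = 1.5e-06; adjusted p = 0.192 with an estimated correlation). Glucose import had 7 of 38 higher and 18 lower, and 6 and 21 after scaling (adjusted p = 9.9e-07; adjusted p = 0.22 with an estimated correlation), and mitochondrial complex I had 4 of 36 higher and 30 lower, and 0 and 35 after scaling (adjusted p = 7.3e-16; adjusted p = 0.145 with an estimated correlation).

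A transcript of 10169 bases annotated as an RNA1 polyprotein of a picorna-like RNA virus (TRINITY_DN13128_c0_g3) had 1937 ± 11 TPM in the infected libraries and 0.303 ± 0.0493 in the controls (adjusted p = 1.4e-10). An unannotated transcript of 264 bases (TRINITY_DN13562_c1_g1) went from 61380 ± 3122 TPM in controls to 8.18 ± 2.27, and another of 444 bases (TRINITY_DN1742_c0_g1) had 1090 ± 16.6 TPM in controls and was listed at 0 in the infected group. These 3 lie outside the naming rule and were chosen after their values were seen.

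Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many higher transcripts as the real split, namely the real one (20775, and at most 0 in any other), 1 gave as many lower ones (4792, and at most 0), and 1 gave as many lists (21, and at most 18). With 10 splits the share is never under 0.1. In limma the other splits had 359 to 426 transcripts at an unadjusted p under 0.05, against 26583 in the real one. Each side of every other split holds 2 libraries of one group and 1 of the other, so part of the difference between the groups stays in its contrast. The 16 to 18 lists that passed in those splits are thus no measure of chance alone. The rest of the difference widens the spread within each side, so the 0 transcripts called there are no measure of chance either.

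The fall of cuticle protein transcripts, with a median log2 change of -3.32, lies far below the -0.21 that the share of viral transcripts would give by dilution, which argues against dilution as its cause. Fewer epidermal cells as the whole cause would lower enzymes made only in those cells about as much. The 19 tested enzymes of chitin synthesis, chitin deacetylation and tanning had a median of -0.00575, with 9 higher and 7 lower. Without chitin synthase 2, at 0.583 TPM in controls, the median of the other 18 was -0.0743 (-0.92 after scaling). The 13 with at least 5 TPM in controls stood at -0.39 (-1.39 after scaling). This lay above the cuticle median by more than their interquartile range of 2.14 (2.17). As a set these enzymes thus fell less than the cuticle proteins. They were picked by name and not shown to be made in epidermis alone, so they cannot decide whether epidermal cells were lost. Loss of epidermal cells as the whole or a partial cause stays open. The sets overlap, with the lower quartile of these 13 at -1.74 and the upper quartile of the cuticle proteins at -1.59. Chitin synthase (-2.23), chitin deacetylase (-2.36) and laccase 2 (TRINITY_DN9726_c0_g2, -3.03, outside the naming rule and chosen after its value was seen) fell, while tyrosine hydroxylase (1.91) rose. A difference in age or moult stage also stays open, since the labels give neither: the 5 cuticle proteins that rose went from 1518 to 3930 TPM, against 244800 TPM lost by the list. Infection itself, which the design names, also stays open and was not tested apart from these. The infected libraries also held 65 transcripts with a microsporidian match that were listed at 0 in the controls. An RNA virus transcript stood at 1937 TPM in the infected libraries against 0.303 in the controls. The controls held 89 transcripts with a fly or mosquito match that were listed at 0 in the infected libraries. For the fall of cuticle proteins and the other differences between the groups, ApNPV therefore cannot be told apart from the sources of these transcripts.

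Viral transcripts appeared at trace level in control libraries: over 35 abundant baculovirus transcripts the ratio of control to infected TPM had a median of 2.87e-05, with quartiles of 2.01e-05 and 3.53e-05, a lowest value of 0 and a highest of 5.78e-05, which reads passed between libraries could give. In the other direction the ratio of infected to control TPM was 4.79e-05 for cuticular protein 11, 9.9e-05 for cuticle protein 66 and 0.000108 for pupal cuticle protein PCP52. It was higher for cuticle protein 1 (0.000274) and a cuticle protein 3-like transcript (0.000943), while TRINITY_DN4017_c0_g1 was listed at 0 in the infected group. All were chosen after their values were seen, and these traces do not tell passed reads from remaining expression. Reads passed between libraries cannot be told apart from a low level of infection in the controls, because either would give low viral values there. For the RNA virus transcript the ratio was 0.000157, and 0.000139 to 0.000186 in single control libraries, above that whole range, which argues against passage at 1 common rate as the source of its trace in the controls.

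Of the transcripts with a fly, microsporidian or mouse match, 89 of 160, 65 of 66 and 8 of 10 were above 0 in all libraries of 1 group and listed at 0 in the other, while others, such as an abundant actin, were found in both. Moth genes with a misleading best match were looked for among the ribosomal proteins. Of 108 fly and microsporidian ones with a protein name, 103 (95.4%) had a further transcript of the same name and number with another best match. Mitochondrial and cytosolic ribosomal proteins can share a number, and fragments of 1 moth gene would also have a further transcript. This share therefore cannot decide whether some were moth transcripts. Material or handling shared by the 3 libraries of a group could account for them. The largest ratio between libraries of a group in the summed TPM of a set was 1.156. These sums ran only over transcripts chosen for being above 0 in all 3 libraries of 1 group. An absence from 1 of the libraries could thus not have shown, and the even share does not decide the question. A microsporidian infection of the infected moths, and a fly or mouse library handled alongside, are examples of this kind, and no biological explanation was tested for either. The source of the fly-matched transcripts in the controls was not determined.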
